A study of Mus musculus with 72 samples.

How the data were processed

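RNA from the livers of wild type male C57BL/6J mice was measured in 72 sequencing libraries. Per the labels' protocols, total RNA was taken up in TRIzol, precipitated, and made into libraries with the TruSeq RNA kit, version 2, which selects polyadenylated RNA and does not mark strand. The titles give each library a feeding regimen (chronic or acute), an arm (control or ethanol), a zeitgeber time (ZT, hours after lights on) and a replicate number. They form 24 groups of 3 libraries, 18 libraries per arm. Chronic libraries were taken at ZT 0, 4, 8, 12, 16 and 20 and acute libraries at ZT 1, 4, 8, 12, 16 and 20. The columns of the acute tables name the earliest time 0 where the sample titles say 1, and the titles were followed. The ethanol doses, the diets and the lengths of feeding are not given in the sources used here. The labels do not say that replicates are separate animals, so every p-value below measures the spread between these libraries, which may be partly technical.

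The authors deposited 4 tables, 1 per regimen and arm, each with 24421 gene symbols. Their FPKM values (fragments per kilobase of transcript, scaled to each library's total) carry no unit in the file headers, and the unit was inferred from the deposited values. In 407 genes with a single annotated transcript, the step of each library was fitted as the most frequent product of low value and transcript length. Of 13545 low values 37.5% lay within 2% of 1 or 2 steps, against 0.701% within the same distance of 1.25 or 2.5 steps. Since the step was fitted to these same values, part of this excess was fixed in advance. That step, the value of 1 fragment, implied 12600000 to 32000000 fragments in the acute control libraries, 16100000 to 43700000 in acute ethanol, 18000000 to 38100000 in chronic control and 11600000 to 40200000 in chronic ethanol. The step fixes the precision of low genes, and intervals built on it would cover counting error only. Summed over genes, FPKM times transcript length (scaled so that 1 is the total a library would give if all its fragments fell on the matched genes at their annotated lengths) was 1.11 to 1.13 in both chronic arms, 1.11 to 1.18 in acute control and 1.12 to 1.27 in acute ethanol, so each library had been scaled to its own total. No scaling between libraries was seen. Per the submitters' processing notes the genome build was mm10. The aligner, the quantifier and the annotation are not given in the sources used here. Per the file headers, the deposited tables also hold a p-value and a q-value per gene from the authors' own rhythm test over the 18 libraries of an arm, with its period, lag, amplitude and other scores, by a tool not given in the sources used here. Only the counts of genes below a threshold were taken from those columns.

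Of the 24421 symbols, 23375 matched the GENCODE M21 annotation of GRCm38, the assembly behind mm10, which supplied transcript lengths and the coordinates given. 6417 symbols were 0 in all libraries. No pair of libraries held identical values (0 pairs), and the highest correlation between libraries was 0.997. Counting without strand, and without a stated rule for reads shared between near-identical genes, leaves the levels of paralogs uncertain. This concerns the Cyp2a, Cyp2b, Cyp2c, Cyp4a, Mup, Gsta, Gstm and Saa families, and Gapdh and ribosomal protein genes, which have many processed pseudogenes.

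Values were analysed as log2(FPKM + 1) with limma 3.58.1 (trended, robust empirical Bayes variances; statmod 1.5.0) in R 4.3.3, since FPKM are not counts. A fold change on this scale understates the change of low genes. Genes with a mean of at least 0.5 FPKM over the libraries of a model were tested, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Each regimen was fitted apart with 12 group means over 36 libraries. Ethanol was compared with control as the mean over the 6 times, at each time, and as the interaction of arm with time. Rhythms were fitted per arm as a cosine and sine with a period of 24 h and tested together, and the difference in rhythm between arms was tested in a model of both arms. Peak times are those of the fitted curve, with delta-method standard errors. The chronic and acute effects were compared in 1 model over all 72 libraries. In that contrast ZT0 of the chronic and ZT1 of the acute regimen stood in for each other.

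Before the data were examined, 38 gene lists were fixed. They cover the core clock with the PAR bZIP factors, ethanol and acetaldehyde oxidation, acetyl-CoA supply, fatty acid synthesis, cholesterol synthesis and uptake, PPAR-alpha targets and fatty acid oxidation, gluconeogenesis and fasting, glycolysis and glucose use, and bile acids. They further cover xenobiotic metabolism, glutathione and NRF2 targets, the unfolded protein and integrated stress responses, heat shock, acute phase, interferon, NF-kB, the tricarboxylic acid cycle, oxidative phosphorylation, cytosolic ribosomal proteins, NAD metabolism, and one-carbon metabolism. Male-biased and female-biased liver genes, immediate early genes, glucocorticoid-responsive genes and cell division genes were also listed. The cell type lists hold markers of pericentral and periportal hepatocytes, Kupffer cells, endothelium, stellate cells, cholangiocytes, B and T cells, neutrophils, erythroid cells, adipocytes, skeletal muscle and exocrine pancreas. Members were counted as passing or not over all genes tested and again adjusted over the list alone. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, all from limma. Genes were named by a rule fixed at the same time. It takes the 8 highest and 8 lowest fold changes per regimen among genes that passed, had a mean of at least 1 FPKM and the same sign at 5 or more of the 6 times, without predicted genes. It adds up to 4 members of each list with the smallest p, the clock genes, the 6 leading genes for differential rhythm per regimen, the 3 highest and 3 lowest at the time with most calls, and the 5 highest and 5 lowest differences between regimens. Any other gene is named only to complete a count of 5 or fewer, after its values were seen. Some genes that the rule takes are not reported here, though they stay in the counts.

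In the chronic regimen every same-numbered control and ethanol library deviated together from its group means (18 of 18 pairs with a correlation over 0.1, 0.112 to 0.542), so the replicate numbers were taken to pair these libraries. The pairing comes from the data, as the labels do not say what a number stands for, and 27 of 36 chronic libraries correlated best with their own number. A block removes only what both arms of a number share. Replicate 1 differed between the chronic arms, with 4.08 to 6.11 FPKM of Rps10 in ethanol and at least 14.7 in control (ZT12). Blocked counts and splits by pair do not remove that difference. The fit without a block stayed the main one, and the blocked value is given beside each chronic result it moved past a threshold or by over 1.5 times.

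Alternatives were upper-quartile rescaling, no filter, a minimum of 5 FPKM, a pseudocount of 0.1, limma without trend and robust variances, the replicate block, a threshold of 0.01, other rhythm tests, leaving time out of the model, and leaving out each library or, for named genes, clock peak times and the difference between regimens, each replicate number. Those added after the data had been seen were every alternative for the calls shared by both regimens except the threshold of 0.01, each replicate number left out for all other results, the chronic ethanol library highest in Mt1 and Mt2 left out, a block within each arm, leaving out 4 acute control libraries together, leaving out ZT1, coding ZT1 as 0, and replicate 3 alone. The methods were tested on simulated data with independent normal noise, a single SD per gene for both arms, and no replicate structure. The simulation therefore does not measure false calls from structure by replicate number, nor power where the arms differ in spread. Over 10413 genes, 92% of 1.5-fold and 98% of 2-fold simulated changes were recovered in the chronic comparison, with 6 false calls. Over 9872 genes the acute comparison recovered 90% and 100%, with 9 false calls. Simulated rhythms with a log2 amplitude of 0.5 were recovered in 76.1% (chronic control), 80.6% (chronic ethanol), 67.2% (acute control) and 64.2% (acute ethanol) of genes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. A transcript length index was computed per library from log2(FPKM + 1) centred on each gene's mean over the 72 libraries. It is the median over 464 genes with transcripts up to 1000 nt minus the median over 2998 genes with transcripts longer than 4000 nt, all with a mean of at least 1 FPKM.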

Results

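Liver RNA of male mice was compared between ethanol and control arms of a chronic and of an acute regimen across the day, to ask how ethanol alters the circadian transcriptome. Each of the 4 arms held 18 libraries, 3 at each of 6 zeitgeber times (ZT, hours after lights on). The value of 1 fragment implied 12600000 to 32000000 fragments per library in acute control, 16100000 to 43700000 in acute ethanol, 18000000 to 38100000 in chronic control and 11600000 to 40200000 in chronic ethanol. Levels are the authors' FPKM. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p-values are from limma. Coordinates refer to GRCm38, and every gene given with coordinates is protein coding.

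Under chronic ethanol, the cytochrome P450 genes of drug metabolism rose most and male-biased liver genes were among those that fell most, averaged over the 6 times (n = 18 libraries per arm). Cyp2b10, a phenobarbital-inducible P450 (chromosome 7, 25897620 to 25926624), was at 0.76 ± 0.989 FPKM (SD) in control and 274 ± 248 in ethanol, a log2 fold change of 6.78 (SE 0.37, adjusted p = 2.57e-13). Cyp2a5, a P450 that hydroxylates coumarin (chromosome 7, 26835305 to 26843548), rose from 172 ± 103 to 2113 ± 543 FPKM, by 3.89 (SE 0.15, adjusted p = 7.69e-17). Hsd3b5, a steroid dehydrogenase found mainly in male liver (chromosome 3, 98618634 to 98630252), went from 84.2 ± 54.1 to 2.9 ± 3.35 FPKM, a log2 fold change of -4.40 (SE 0.39, adjusted p = 3.24e-09). Fabp5, a fatty acid binding protein (chromosome 3, 10012548 to 10016607), went from 180 ± 115 to 14.4 ± 5.71 FPKM (log2 fold change -3.39, SE 0.20, adjusted p = 1.25e-12).

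The other leading genes that rose were Cyp2b9 (6.06, SE 0.47), Cyp2a4 (4.42, SE 0.45), Cyp2a22 (4.05, SE 0.26), Cyp2c29 (3.43, SE 0.22), Gstm3 (3.04, SE 0.24) and Gsta2 (2.92, SE 0.19), with adjusted p from 4.39e-12 for Cyp2c29 and Gsta2 to 3.13e-08 for Cyp2a4. Cyp2c29 (chromosome 19, 39269405 to 39330713) went from 79.1 ± 26.1 to 904 ± 447 FPKM. Gsta2, a glutathione transferase (chromosome 9, 78331018 to 78355788), went from 17.6 ± 17 to 121 ± 46.3 FPKM. The other leading genes that fell were Tff3, a secreted trefoil peptide (-3.31, SE 0.20; chromosome 17, 31125306 to 31129646), Cyp4a12b (-2.56, SE 0.29), the major urinary proteins Mup21 (-2.55, SE 0.30) and Mup20 (-1.96, SE 0.20), complement component C6 (-1.99, SE 0.17) and Cyp4a12a (-1.97, SE 0.27). Their adjusted p ran from 1.62e-12 for Tff3 to 5.78e-06 for Cyp4a12a. In total 2108 of 10413 genes passed, 769 higher and 1339 lower, and 3529 had an unadjusted p under 0.05. With the replicate number as a block 3646 genes passed, 1402 higher and 2244 lower. Leaving out replicate 1 gave 2251 genes (1002 higher, 1249 lower; 1409 of them among the 2108) and leaving out replicate 2 gave 828.

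Of 16 measured genes of xenobiotic metabolism, 14 rose under chronic ethanol and none of the list fell, and the same 14 and 0 were found adjusted over the list alone. Besides Cyp2b10, Cyp2b9 and Cyp2c29, Cyp1a2, an arylamine-oxidising P450, rose by 1.68 from 169 to 532 FPKM (adjusted p = 2.58e-13). The list stood above other genes by camera (adjusted p = 1.45e-23), and adjusted p = 4.04e-04 with an estimated correlation. Of 15 genes of glutathione metabolism and NRF2 targets, 13 rose (13 adjusted over the list alone) and none fell, among them the glutathione transferases Gsta2, Gstm3, Gstm1 (2.06, 901 to 3.84e+03 FPKM) and Gsta4 (1.51). Camera gave an adjusted p of 2.67e-18, and adjusted p = 0.00597 with an estimated correlation. With the replicate block, both lists held with an estimated correlation too (adjusted p = 0.00523 for xenobiotic metabolism and 0.0347 for glutathione).

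Of 13 male-biased liver genes, 10 fell (11 adjusted over the list alone), led by Hsd3b5, Cyp4a12b, C6 and Cyp4a12a, and none rose (camera adjusted p = 3.52e-10; adjusted p = 0.136 with an estimated correlation). Of 7 female-biased liver genes, 5 rose (6 adjusted over the list alone) and none fell. Among them were Cyp2b9, Cyp2a4, Cyp2b13 (2.42) and the flavin monooxygenase Fmo2 (0.71, named after its values were seen), and Cyp2b9 and Cyp2b13 also stand in the xenobiotic list. Camera gave an adjusted p of 9.81e-08 for the female-biased list, and adjusted p = 0.031 with an estimated correlation, which was 0.123 with the replicate block. Single control libraries stood apart in these genes. Chronic control ZT20 replicate 1 held 101 FPKM of Cyp2a4 against at most 2.0 in the other chronic control libraries, 9.18 of Cyp2b9 against at most 0.900, and 1.0 of Hsd3b5 against at least 23.3.

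**Figure D1:**
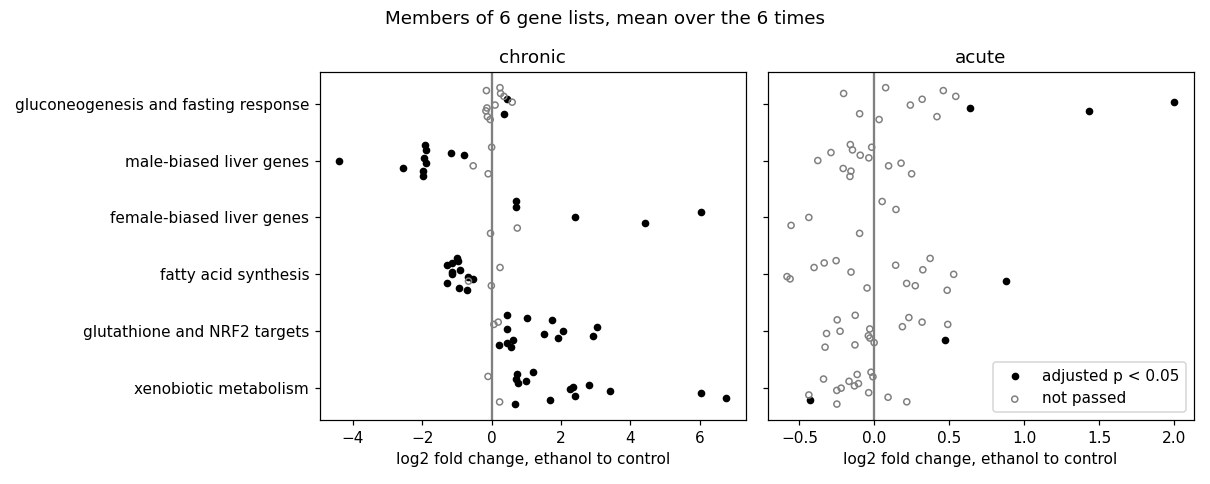
Log2 fold change of ethanol against control for each measured member of 6 gene lists, per regimen, as the mean over the 6 times on the log2(FPKM + 1) scale; filled points passed at an adjusted p of 0.05, and the horizontal scales differ between panels. In the chronic regimen 14 of 16 xenobiotic genes and 13 of 15 glutathione and NRF2 genes are filled and above 0, and 12 of 15 fatty acid synthesis genes are filled and below 0.

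Genes of lipogenesis fell under chronic ethanol. Of 15 genes of fatty acid synthesis 12 fell (13 adjusted over the list alone) and none rose, including the elongase Elovl5 (-1.30, 704 to 284 FPKM, adjusted p = 8.37e-10), the lipase-like Pnpla3 (-1.28), the acyltransferase Gpam (-1.15) and the acetyl-CoA carboxylase Acacb (-0.94). Without replicate 1 of every group 12 of the 15 fell and Dgat2 rose (0.17, adjusted p = 0.0492); 7 fell without replicate 2 and 8 without replicate 3. Of the 12, 10 were lower in replicate 1 and all 12 in each other replicate number. The desaturase gene Scd1, which with Dgat2 is named after its values were seen, was among the 12 but lay higher with ethanol in replicate 1, at 716 ± 249 FPKM in control and 1017 ± 587 in ethanol (SD, n = 6). In replicate 2 it was at 538 ± 146 and 137 ± 72.5 and in replicate 3 at 520 ± 119 and 148 ± 49.7, and it did not pass without either (adjusted p = 0.42 without replicate 2 and 0.352 without replicate 3 in limma). Of 11 genes of acetyl-CoA supply 6 fell (9 adjusted over the list alone), led by ATP citrate lyase, Acly (-1.66, 168 to 53.2 FPKM, adjusted p = 8.52e-07; chromosome 11, 100476353 to 100528000), with Dlat (-0.77), Slc25a1 (-0.43) and Pdhx (-0.29). Of 12 genes of glycolysis and glucose use 6 fell (8 adjusted over the list alone), among them glucose-6-phosphate dehydrogenase, G6pdx (-1.45, 12.7 to 3.84 FPKM), pyruvate kinase, Pklr (-0.75), and Gapdh (-0.42), and 2 fell without replicate 2 and 3 without replicate 3. Camera called these 3 lists (adjusted p = 9.81e-08 for fatty acid synthesis, 2.81e-05 for acetyl-CoA supply and 4.90e-04 for glycolysis). None of these calls held, with adjusted p = 0.101, 0.177 and 0.177 with an estimated correlation. Of 23 genes of cholesterol synthesis and uptake 7 fell (10 adjusted over the list alone), among them Fdps (-0.70), Insig1 (-0.68) and Pmvk (-0.67), and 1 rose (1 fell and 1 rose without replicate 2); the list did not pass camera (adjusted p = 0.0619, 0.0479 without replicate 1, and 0.736 with an estimated correlation).

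Among 10 genes of ethanol and acetaldehyde oxidation, the aldehyde dehydrogenase Aldh1a1 rose by 1.13 (311 to 666 FPKM, adjusted p = 7.58e-09) and the alcohol dehydrogenase Adh1 by 0.32 (adjusted p = 0.021), while Adh4 fell (-0.41, adjusted p = 0.0292). The counts were the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.256). Of 8 pericentral hepatocyte markers Cyp1a2, the glutamate transporter Slc1a2 (0.83) and Oat (0.53, named to complete the count) rose and Rgn (-0.54) and Gulo (-0.40) fell, also adjusted over the list alone (camera adjusted p = 0.0317, which was 0.0688 with the replicate block and 0.0833 without replicate 1, and adjusted p = 0.517 with an estimated correlation). Of 20 PPAR-alpha targets and genes of fatty acid oxidation 3 rose (4 adjusted over the list alone) and 7 fell. The fatty acid hydroxylases Cyp4a14 (2.38, 123 to 637 FPKM, adjusted p = 2.27e-04) and Cyp4a10 (1.49) and the lipase inhibitor Angptl4 rose, and the receptor gene Ppara (-0.55) and the ketone body enzyme Bdh1 (-0.53) fell (camera adjusted p = 0.491). Of 12 genes of gluconeogenesis and fasting, Foxo1 (0.37) and Irs2 (0.44, adjusted p = 0.0461) rose (1 adjusted over the list alone; camera adjusted p = 0.143). Of 14 bile acid genes, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 0.86 (47.8 to 88.2 FPKM, adjusted p = 0.00314) and the exporter Abcc2 by 0.19, and the uptake transporter Slco1a1 (-1.88), the repressor Nr0b2 (-0.69, named to complete the count) and Cyp27a1 (-0.39) fell. The counts were the same adjusted over the list alone, and camera gave an adjusted p of 0.589. Of the 25 genes called in these 5 lists 17, 11 and 13 passed without replicate 1, 2 and 3. In each case 9 passed, among them Aldh1a1, Cyp1a2, Slc1a2, Cyp4a14, Cyp4a10, Ppara, Cyp7a1 and Slco1a1.

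Heat shock and glucocorticoid-responsive genes rose in part. Of 10 heat shock genes 5 rose (8 adjusted over the list alone), namely Hspb1 (0.55), Hsp90aa1 (0.47), Dnaja1 (0.33), Hspd1 (0.29) and, named to complete the count, Hsph1 (0.47). Without replicate 2 limma called 0 of them, with 2 at an unadjusted p under 0.05, and without replicate 3 it called 2. Of 11 glucocorticoid-responsive genes 4 rose (5 adjusted over the list alone), namely the metallothioneins Mt1 (1.96, 42.4 to 249 FPKM) and Mt2 (1.90), Tsc22d3 (0.58) and Fkbp5 (0.51); metallothioneins also respond to metals. The chronic ethanol library at ZT12, replicate 1, held 2015 FPKM of Mt1 and 932 of Mt2, against at most 395 and 176 in the other 17. Without it the ethanol means were 145 and 63.5 FPKM and the log2 fold changes 1.76 (adjusted p = 7.20e-05) and 1.69 (3.30e-04). Camera gave adjusted p of 1.23e-04 for heat shock and 0.00297 for the glucocorticoid list, and for both adjusted p = 0.268 with an estimated correlation. Of 18 genes of the unfolded protein and integrated stress responses, Asns (1.42), Trib3 (0.54) and Atf5 (0.36) rose and Xbp1 fell (-0.38), with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.087, and 0.0174 without replicate 1). Of 15 acute phase genes Orm3 (2.11, 1.96 to 15.2 FPKM), Itih4 (0.49) and, to complete the count, Lcn2 (1.13) and Orm1 (0.44) rose, and Apcs (-0.98) and Fga (-0.27) fell, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.552). Of 7 NF-kB and chemokine genes Ccl2 rose (0.69) and Il1b fell (-0.43), the same counts as adjusted over the list alone (camera adjusted p = 0.257). Among 9 interferon genes limma called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. Of 6 immediate early genes Dusp1 (-0.68) and Btg2 (-0.56) fell, also adjusted over the list alone (camera adjusted p = 0.402). Of the 23 genes called in these lists 21, 8 and 9 passed without replicate 1, 2 and 3, and Mt1, Mt2, Asns, Orm3, Apcs and Dusp1 in each case.

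A few genes of mitochondrial respiration passed under chronic ethanol, and none of them did without replicate 1 or without replicate 2. Of 25 oxidative phosphorylation genes, Ndufb8 (-0.49), Uqcrfs1 (-0.30), Atp5a1 (-0.20) and Atp5b (-0.18) fell, also adjusted over the list alone, with a camera adjusted p of 0.0619, which was 0.00256 with the replicate block and 0.00257 without replicate 3. Limma called 0 of the 25 without replicate 1 and 0 without replicate 2, with 2 and 7 at an unadjusted p under 0.05, and 2 without replicate 3. The 4 genes had a median log2 difference of -0.68 in replicate 1, -0.14 in replicate 2 and -0.03 in replicate 3, where 2 of the 4 were lower. Of 23 cytosolic ribosomal protein genes limma called 0, also adjusted over the list alone, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.137, 0.0277 with the block and 0.00544 without replicate 3). With an estimated correlation the adjusted p was 0.736 for oxidative phosphorylation and 0.754 for the ribosomal list. The messages of both lists are mostly short, and the 6 replicate 1 libraries of chronic ethanol held fewer short transcripts. Their index of short minus long transcripts ran from -0.589 to -0.288, and their level of the ribosomal gene Rps10 from 4.08 to 6.11 FPKM. In 4 replicate 1 libraries of acute control, at ZT4 to ZT16, the index ran from -0.72 to -0.429 and Rps10 from 3.3 to 5.61 FPKM, against -0.286 to 0.983 and 9.2 to 92.1 FPKM in the other 62 libraries. Hcfc1r1, named after its values were seen, was high in both sets (37 to 51.1 and 28 to 45 FPKM, against 3.85 to 33.2 in the 62). The 33.2 was in acute control ZT1 replicate 1, which had the highest index, 0.983. The libraries that stand apart thus differ in more than short transcripts. The other 62 were not uniform either. Rps10 was at 14.7 to 35.0 FPKM in chronic control replicate 1 and 43.0 to 69.3 in its replicates 2 and 3. In acute control it was at 9.2 to 19.3 in replicate 2 and 60.1 to 74.4 in replicate 3. Leaving out the libraries of low index therefore does not remove all structure by replicate number.

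**Figure D2:**
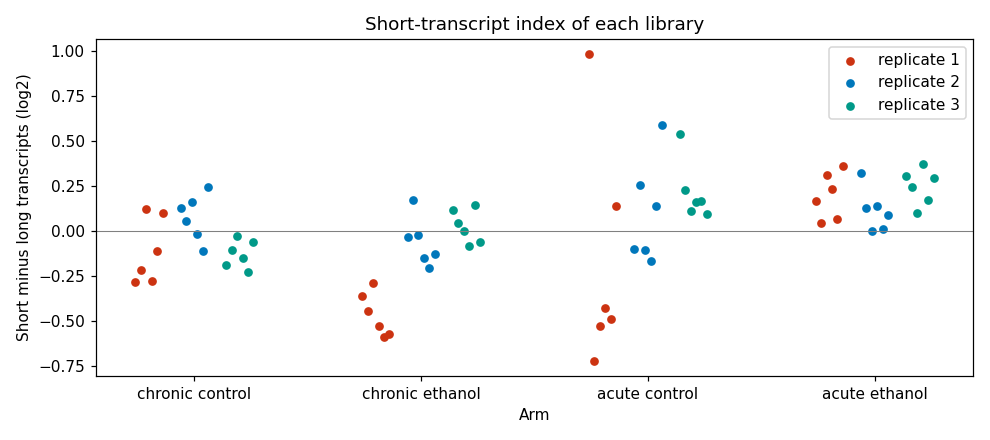
Index of short minus long transcripts per library (log2), by arm and coloured by replicate number. The 6 replicate 1 libraries of chronic ethanol lie between -0.589 and -0.288 and 4 of acute control between -0.72 and -0.429, below the other 62.

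At single times of the chronic regimen (n = 3 libraries per arm), most genes passed at ZT12, 221 (80 higher, 141 lower). There Cyp2b10 was higher by 7.18 (0.304 to 286 FPKM, limma adjusted p = 2.13e-05), Cyp2a4 by 5.61 (adjusted p = 0.00521) and Cyp2b9 by 5.6 (adjusted p = 0.00883). Hsd3b5 (-4.63, 82.5 to 2.72 FPKM, limma adjusted p = 0.00942), Tff3 (-4.36, 37.6 to 0.863 FPKM, adjusted p = 9.35e-06) and Fabp5 (-4.24, 252 to 11.9 FPKM, adjusted p = 9.61e-06) were lowest. The counts at the other times were 164 at ZT0 (84 higher, 80 lower), 138 at ZT4 (70 and 68), 129 at ZT8 (56 and 73), 109 at ZT16 (43 and 66) and 75 at ZT20 (48 and 27). The 836 calls over the 6 times were 2087 with the replicate block and 83 without replicate 2.

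Chronic ethanol altered the daily pattern of clock genes. The activator Arntl (Bmal1; chromosome 7, 113207465 to 113314126) peaked at 21.3 h after lights on in control and at 18.9 h in ethanol (-2.41 h, SE 0.554; limma adjusted p for a difference in rhythm = 0.0264). The repressor Per2 (chromosome 1, 91415982 to 91459324) peaked at 14.2 and 10.9 h (-3.31 h, SE 0.653, adjusted p = 0.0147), and Nr1d1, encoding REV-ERB-alpha (chromosome 11, 98767932 to 98775333), at 5.99 and 2.90 h (-3.09 h, SE 0.559, adjusted p = 0.0013). The clock output factor Dbp (chromosome 7, 45705088 to 45710203) peaked at 9.29 and 6.46 h (-2.83 h, SE 0.51, adjusted p = 0.00506). Over 12 clock genes rhythmic in both arms the fitted peak was earlier in ethanol in each, by a mean of -2.76 h (range -3.77 to -1.81 h). Taken separately, the 3 replicate series gave -3.08, -2.14 and -3.23 h, a mean of -2.82 ± 0.591 h (SD, n = 3).

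Cry1 (-3.77 h, adjusted p = 2.82e-04), Per3 (-3.23 h, 4.67e-04) and Tef (-1.81 h, 0.00517) also passed the rhythm test, while Clock (-3.48 h, 0.0911), Npas2 (-1.85 h, 0.096), Per1 (-2.44 h, 0.389) and Ciart (-2.13 h, 0.196) did not. Without replicate 3 limma called 0 of 10404 genes in this test, with 922 at an unadjusted p under 0.05, so no clock gene passed there. Without replicate 2 it called 1 gene. The fitted log2 amplitude of the 12 genes averaged 1.43 in control and 1.0 in ethanol, and was lower in ethanol in all 12 (median ratio 0.708). At ZT12 Dbp was lower (-2.02, adjusted p = 0.023), Per3 lower (-1.41, 0.013) and Arntl higher (1.42, 0.0174) in ethanol. In the mean over the times, 4 of the 18 clock list genes fell, among them Bhlhe40 (-0.46), Cry1 (-0.44) and Npas2 (-0.31), and the same 4 adjusted over the list alone (camera adjusted p = 0.634). Of the 4, 3, 1 and 2 passed without replicate 1, 2 and 3, Cry1 in each case.

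**Figure D3:**
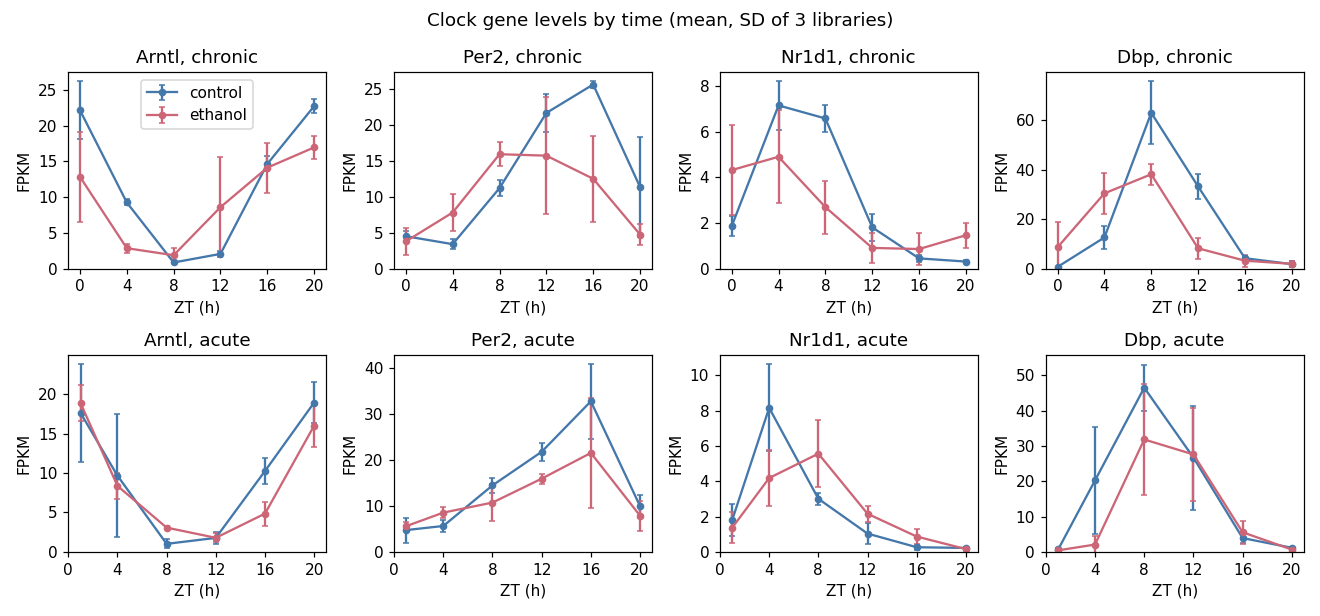
FPKM of Arntl, Per2, Nr1d1 and Dbp against zeitgeber time in hours, chronic and acute, control and ethanol; points are means of 3 libraries and bars their SD. In the chronic regimen the fitted peaks of the 4 genes are earlier in ethanol, by -2.41 to -3.31 h.

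**Figure D4:**
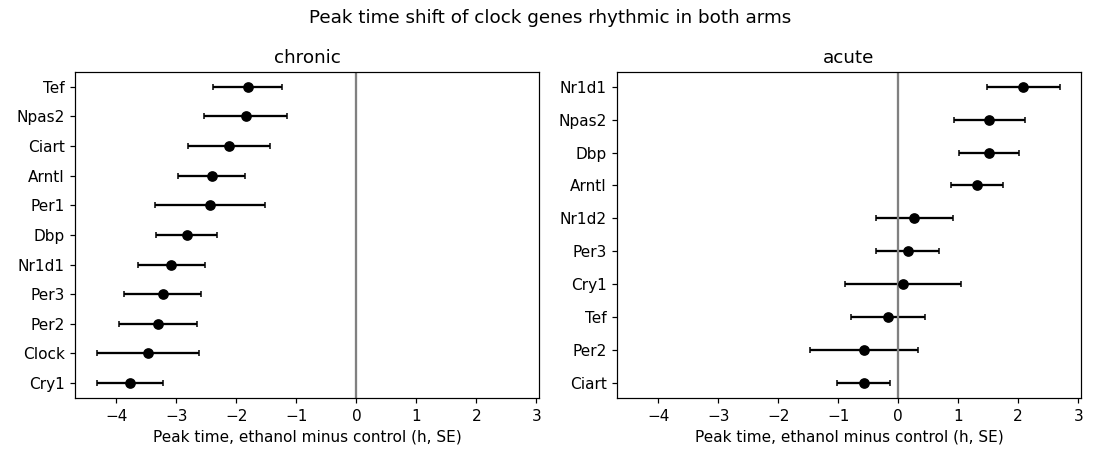
Difference in fitted peak time, ethanol minus control in hours, for 11 clock genes of the chronic and 10 of the acute regimen, with SE bars; 1 gene of each regimen is not drawn. All drawn chronic values lie below 0 and the acute values on both sides of 0.

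Rhythms of other genes differed as well. The water channel gene Aqp11 (chromosome 7, 97724006 to 97738289) had a log2 amplitude of 0.50 in chronic control and 0.03 in ethanol (adjusted p = 8.52e-05), and the glutamine transporter gene Slc38a3 (chromosome 9, 107650634 to 107669530) 0.77 and 0.38, with a peak shifted by -4.16 h (adjusted p = 2.82e-04). Tor3a went from 0.66 to 0.24 (adjusted p = 2.82e-04), Cry1 from 1.16 to 0.78 and Per3 from 1.83 to 0.94. In all, 81 of 10413 genes differed in rhythm (206 with the replicate block) and 1254 had an unadjusted p under 0.05. The ethanol effect differed between times in 21 genes (52 with the block), with Slc38a3 and Aqp11 leading (adjusted p = 0.00309 for each), followed by Per3 (0.00509). Without replicate 2 the 81 became 1 and the 21 became 1, and without replicate 3 they became 0 (922 at an unadjusted p under 0.05 in limma) and 1. Leaving out 1 library moved the 81 to between 40 and 53 for 11 libraries, and the 21 to between 12 and 39 for 4. A rhythm was called in 2218 of 10417 genes in chronic control and 132 of 10375 in chronic ethanol (3321 and 602 with the block; 49 to 87 in ethanol without any 1 of 10 ethanol libraries). Without replicate 2 these counts were 508 and 11, and without replicate 3 1047 and 6. In the authors' deposited tables, 818 of 24421 genes in chronic control and 11 in chronic ethanol had a q-value under 0.05.

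Under acute ethanol, genes of gluconeogenesis and sugar metabolism rose, averaged over the 6 times (n = 18 libraries per arm). Igfbp1, an insulin-repressed binding protein (chromosome 11, 7197782 to 7202546), went from 4.81 ± 3.6 to 36.2 ± 49.6 FPKM, a log2 fold change of 2.0 (SE 0.37, adjusted p = 0.0024). G6pc, glucose-6-phosphatase (chromosome 11, 101367561 to 101377903), rose from 17.4 ± 8.52 to 70.1 ± 66.5 FPKM (1.43, SE 0.17, adjusted p = 1.63e-05). Gpi1, glucose-6-phosphate isomerase (chromosome 7, 34201330 to 34230336), rose from 136 ± 29.7 to 368 ± 281 (1.08, SE 0.13, adjusted p = 2.07e-05). Upp2, uridine phosphorylase 2 (chromosome 2, 58567298 to 58792971), led the fall, from 97 ± 74.3 to 37.1 ± 22.8 FPKM (-1.21, SE 0.24, adjusted p = 0.00542).

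Further genes that led the rise were Slc34a2, a phosphate transporter (1.29, adjusted p = 0.00545), Cabp2 (1.14, 9.78e-04), the transcription factors Bhlha15 (1.06, 0.00138) and Junb (1.04, 0.0098). Those that led the fall were Serpina6, corticosteroid-binding globulin (-1.03, 0.011; 55.3 to 25.7 FPKM), Nxpe2 (-0.98, 0.00458), Prg4 (-0.94, 0.046), Chrna4 (-0.94, 0.0344), Cyp2a5 (-0.85, 0.0209; 351 to 201 FPKM) and Arrdc3 (-0.77, 0.034). In total 300 of 9872 genes passed, 148 higher and 152 lower, and 1944 had an unadjusted p under 0.05. Of the 300, 49.3% were higher, and of the 356 with upper-quartile rescaling 65.7% (234 higher, 122 lower). The count was 88 without replicate 1 (71 higher, 17 lower), 35 without replicate 2, 68 without the 4 acute control libraries of low index, 169 to 199 without 1 of 7 single libraries and 533 without acute ethanol ZT16 replicate 2. Of the 8 leading genes that rose, 7, 4 and 5 passed without replicate 1, 2 and 3 and 8 without those 4 libraries. G6pc, Gpi1 and Bhlha15 were among them each time, while Igfbp1 did not pass without replicate 2 (adjusted p = 0.094) and Junb without any 1 number (0.0544 to 0.0974). Of the 8 leading genes that fell, 2 passed without replicate 1, 0 without replicate 2, 2 without replicate 3 (limma; 8 at an unadjusted p under 0.05 each time) and 3 without the 4 libraries.

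Of 12 genes of gluconeogenesis and fasting 3 rose (4 adjusted over the list alone), G6pc, Igfbp1 and the transaminase Got1 (0.63, adjusted p = 0.0476). Of 12 genes of glycolysis and glucose use 2 rose, among them Pgd, a pentose phosphate pathway dehydrogenase (0.83, 36.9 to 90.2 FPKM, adjusted p = 9.78e-04), and 1 fell, with 5 higher and 2 lower adjusted over the list alone. Of 11 genes of acetyl-CoA supply 1 rose (4 adjusted over the list alone), the pyruvate dehydrogenase subunit Pdhb (0.66, 34.2 to 62.9 FPKM, adjusted p = 2.44e-04). Camera called these lists (adjusted p = 5.45e-05, 0.00436 and 0.00439; the last 2 were 0.0626 and 0.155 without replicate 3), and none held, with adjusted p = 0.229, 0.463 and 0.482 with an estimated correlation. Of 10 genes of ethanol and acetaldehyde oxidation 3 fell (5 adjusted over the list alone). Cyp2e1, the ethanol-oxidising P450 (chromosome 7, 140763739 to 140774987), fell from 5.36e+03 to 3.74e+03 FPKM (-0.51, adjusted p = 0.00292), with catalase, Cat (-0.45, 0.0409), and Adh7 (-0.38, 0.0271). Limma called 1, 0 and 0 of the 10 without replicate 1, 2 and 3, with 4, 4 and 5 at an unadjusted p under 0.05. Camera gave an adjusted p of 0.00114, and adjusted p = 0.318 with an estimated correlation. Of 8 pericentral hepatocyte markers Cyp2e1 and Cyp1a2 (-0.43, 0.0412) fell (3 adjusted over the list alone; camera adjusted p = 0.00377, and adjusted p = 0.318 with an estimated correlation). Of the 11 genes called in these 5 lists 7, 3 and 4 passed without replicate 1, 2 and 3, G6pc and Pdhb among them each time.

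Some immediate early and stress genes rose under acute ethanol. Of 6 immediate early genes Junb and the phosphatase Dusp1 (0.50, adjusted p = 0.00865) rose (4 adjusted over the list alone), and of 11 glucocorticoid-responsive genes Pfkfb3 (0.68, 0.0428) and Cdkn1a (0.49, 0.0381) rose (5 adjusted over the list alone). Camera gave an adjusted p of 1.01e-04 for each list, and for each adjusted p = 0.229 with an estimated correlation. Of 18 genes of the unfolded protein and integrated stress responses 1 rose, Trib3 (0.67, 0.00703), and 2 adjusted over the list alone (camera adjusted p = 1.01e-04; adjusted p = 0.318 with an estimated correlation). Of 15 glutathione and NRF2 genes 1 rose, glutathione synthetase, Gss (0.47, 0.00785), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.723). Of 15 xenobiotic genes 1 fell, Cyp1a2, also adjusted over the list alone (camera adjusted p = 0.169). Of 8 interferon genes 3 fell, among them Ifi44 (-0.40, 0.0343) and Irf7 (-0.31, 0.0379), with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.153). Of the 10 genes called in these 6 lists 1 passed without replicate 1, 1 without replicate 2 and 1 without replicate 3, with 10 at an unadjusted p under 0.05 each time, and no gene passed in every case.

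In lipid and bile acid metabolism under acute ethanol, single genes passed. Elovl6, a fatty acid elongase, rose by 0.88 (adjusted p = 0.0398), as 1 of 15 genes of fatty acid synthesis (2 adjusted over the list alone; camera adjusted p = 0.207, and 1.30e-04, high, without replicate 1). Angptl4 rose by 0.69 (0.0384), as 1 of 20 PPAR-alpha targets, also adjusted over the list alone (camera adjusted p = 0.148, and 0.0106, high, without replicate 2). Of 14 bile acid genes Cyp8b1 rose (0.48, 0.0304) and Cyp27a1 fell (-0.26, 0.0224), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.379). Of these 4 genes 3, 1 and 0 passed without replicate 1, 2 and 3 in limma, with 4, 3 and 4 at an unadjusted p under 0.05. Limma called 0 of 23 cholesterol genes, 0 of 10 heat shock genes, 0 of 25 oxidative phosphorylation genes and 0 of 24 ribosomal genes, with 5, 3, 2 and 6 of them at an unadjusted p under 0.05 and 0 called adjusted over each list alone. Camera placed cholesterol (adjusted p = 0.025) and heat shock (0.0206) low and oxidative phosphorylation (6.13e-04) and ribosomal genes (6.31e-06) high. None held, with adjusted p = 0.659, 0.482, 0.574 and 0.463 with an estimated correlation. Cholesterol was at 0.168 without replicate 3, and heat shock at 0.0644 without replicate 1 and 0.0626 without replicate 3. Oxidative phosphorylation and ribosomal genes have mostly short messages. Without replicate 1 their adjusted p was 0.558 for oxidative phosphorylation and 0.0152 for the ribosomal list, and without the 4 acute control libraries of low index 0.365 and 0.0515.

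At single times of the acute regimen (n = 3 libraries per arm), most genes passed at ZT4, 172 (133 higher, 39 lower). Slc34a2 was higher there by 3.48 (0.818 to 20.4 FPKM, limma adjusted p = 0.00168), Frmd8 by 3.03 (1.06 to 15.9 FPKM, adjusted p = 2.16e-06; chromosome 19, 5849702 to 5875274) and Lpin1, a phosphatidate phosphatase, by 2.74 (6.67 to 47.9 FPKM, 0.00788). Dbp (-2.82, 20.3 to 2.08 FPKM, limma adjusted p = 0.00168), Osgin1 (-2.26, 374 to 90.2 FPKM, 0.0434) and Hykk (-1.26, 26.5 to 10.2 FPKM, 0.031) were lowest. At ZT1, 15 genes passed, 14 higher and 1 lower, Ier5 (-0.78, adjusted p = 0.0146), and at ZT8 36, 35 higher and 1 lower, Dqx1 (-0.91, 0.0316), both named after their values were seen. At ZT12 2 genes passed, both higher, among them Gpi1 (1.82, 140 to 499 FPKM, 0.031). Limma called 0 genes at ZT16 and 0 at ZT20, where 1227 and 412 had an unadjusted p under 0.05. The 225 calls over the times were 22 without replicate 3, 127 to 138 without 1 of 3 single libraries at ZT4, and 499 without acute ethanol ZT16 replicate 2.

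The acute effect of single genes varied with time. The difference in G6pc was 3.89 at ZT1, 2.59 at ZT4, 1.34 at ZT8 and -0.96 at ZT20, and the effect differed between times (adjusted p = 8.99e-04). The test of this interaction passed for 42 of 9872 genes, led by Dusp1 (1.29e-04; 2.64 at ZT1), G6pc and Frmd8 (8.99e-04). Gpi1 (0.0327) was among them. In the test of differential rhythm 90 genes passed, and 1134 had an unadjusted p under 0.05. The fitted peak of Agpat6 moved from 13.8 to 5.31 h (adjusted p = 0.00157) and that of the lipogenic regulator Thrsp (chromosome 7, 97412938 to 97417730) from 13.5 to 7.21 h (0.00781). The log2 amplitude of Pgd went from 0.07 to 1.28 (0.00781) and of Aprt from 0.08 to 0.71 (0.00816), and Slc13a2 passed as well (0.00781). Without replicate 2 the 42 became 2 and the 90 became 0, and without replicate 3 both became 0, with 658 rhythm genes at an unadjusted p under 0.05 in limma in the first case and 305 interaction and 826 rhythm genes in the second. Without 1 of 5 single libraries the 42 became 20 to 100, and without 1 of 9 the 90 became 45 to 58. The acute control libraries of low index were all taken at ZT4 to ZT16, so this library property varied with time in 1 arm and may enter both tests.

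Under acute ethanol the clock genes peaked earlier or later with no common direction. Over 11 genes rhythmic in both acute arms the mean shift was 0.444 h (range -0.741 to 2.08 h), with 7 later and 4 earlier, and the 3 replicate series gave 0.357, 0.282 and 0.789 h (mean 0.476 ± 0.274 h SD, n = 3). Nr1d1 peaked 2.08 h later (SE 0.605, adjusted p = 0.187), Npas2 1.52 h (0.409), Dbp 1.52 h (SE 0.5, 0.282) and Arntl 1.32 h later (SE 0.432, 0.192), and none of the 11 genes passed the limma test of differential rhythm. The mean log2 amplitude was 1.4 in control and 1.2 in ethanol, lower in ethanol in 9 of 11 (median ratio 0.814). In the mean over the times limma called 0 of the 18 clock list genes, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.6). A rhythm was called in 531 of 9887 genes in acute control and 1903 of 9822 in acute ethanol (97 and 470 without replicate 2). In acute control the replicate 1 libraries had a low index at ZT4 to ZT16 (-0.72 to -0.429). At ZT1 (0.983) and ZT20 (0.138) they did not. This library property thus varied with time of day within the arm, and the rhythm tests cannot tell it apart from a rhythm there. Of 24421 genes, 121 in acute control and 270 in acute ethanol had a q-value under 0.05 in the authors' deposited tables.

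Among named genes, the chronic and acute effects differed most in P450 genes of the Cyp2a and Cyp2b families, and in Hsd3b5, Fabp5 and Tff3. The chronic minus acute difference in log2 fold change was 6.69 for Cyp2b10 (SE 0.482, adjusted p = 7.80e-16; 6.78 chronic, 0.09 acute) and 4.74 for Cyp2a5 (SE 0.262, adjusted p = 3.82e-20), which rose by 3.89 in the chronic and had a fold change of -0.85 in the acute regimen. For Hsd3b5 it was -4.02 (SE 0.49, adjusted p = 1.93e-08; -4.40 and -0.38) and for Fabp5 -3.88 (SE 0.314, adjusted p = 5.99e-14; -3.39 and 0.49). In acute control, 1 library stood apart in these genes, ZT16 replicate 1, with 166 FPKM of Cyp2a4 against at most 2.71 in the others, 57.2 of Cyp2b9 against at most 0.993, and 47.0 of Hsd3b5 against at least 121. In total 1794 of 10200 genes differed between regimens, 872 with a higher and 922 with a lower chronic effect. The count was 3019 with the replicate block, 822 without replicate 1 and 884 without the 4 acute control libraries of low index.

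Some genes passed in both regimens. Of 9773 genes tested in both, 17 rose in both, against 10.4 for independent lists, including Angptl4, Gss, Slc34a2 and Trib3. In both, 28 fell, against 20, including Cyp27a1, Arrdc3, Chrna4 and Nxpe2. In opposite directions, 16 rose in the chronic and fell in the acute regimen, against 11.2, including Cyp1a2, Cyp2a5 and Serpina6, and 34 did the reverse, against 18.5, including Dusp1 and Pdhb. The 45 calls shared in direction became 13, 6 and 1 without replicate 1, 2 and 3, 127 with the replicate block and 14 without the 4 acute control libraries of low index. The 16 and 34 calls in opposite directions were not recounted in these settings, so how far they rest on replicate 1 was not tested. Across the 9773 genes, which are not independent replicates, the chronic and acute fold changes had a Pearson correlation of -0.165 and a Spearman correlation of -0.286. Within replicate 1 alone the Pearson correlation was -0.596, within replicate 2 alone 0.00141 and within replicate 3 alone 0.0395, and the negative relation did not hold within replicates 2 and 3.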

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

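The tests of rhythm counts without replicate 1 (ratios 14 and 6.41) were chosen after those counts had been seen. So were the exclusion of a bound on the blocked residual SD, which the block makes void, the exclusion of the splits of shared calls, the list splits that part every pair, and the rule that the range over left-out replicates must also pass a bound before an explanation is excluded, which left 1 test open that would otherwise have been decided. All other tests below were written before their values were seen.

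The ethanol effect differed between regimens, by a test of the difference itself, in 10 named genes. The chronic minus acute log2 fold change was 6.69 for Cyp2b10, 6.49 for Cyp2b9, 4.98 for Cyp2a4, 4.74 for Cyp2a5 and 4.14 for Cyp2a22. It was -4.02 for Hsd3b5, -3.88 for Fabp5, -3.62 for Tff3, -2.62 for Mup21 and -2.35 for Cyp4a12b (adjusted p from 3.82e-20 for Cyp2a5 to 8.66e-07 for Cyp4a12b, limma). The effect also differed between times in 21 genes of the chronic and 42 of the acute regimen.

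Gene lists differed between regimens by camera as well. Higher chronic than acute effects were called for xenobiotic metabolism (adjusted p = 1.21e-23), glutathione and NRF2 targets (6.48e-14), female-biased genes (7.62e-07), heat shock (4.95e-05), pericentral markers (9.34e-04) and ethanol oxidation (0.00469). Lower chronic than acute effects were called for male-biased genes (4.09e-11), acetyl-CoA supply (5.65e-07), fatty acid synthesis (1.50e-06), glycolysis (2.00e-06), ribosomal proteins (1.39e-04), oxidative phosphorylation (5.15e-04) and immediate early genes (0.0037). With an estimated correlation xenobiotic metabolism (adjusted p = 1.40e-05), glutathione (0.00251) and female-biased genes (0.0373) held. The others did not, with adjusted p = 0.0577 for male-biased genes and glycolysis, 0.077 for acetyl-CoA supply, 0.15 for fatty acid synthesis, 0.158 for heat shock, pericentral markers and immediate early genes, 0.187 for ethanol oxidation, 0.505 for ribosomal proteins and 0.582 for oxidative phosphorylation.

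Across genes the chronic and acute effects were negatively correlated (-0.165). For opposite responses to the 2 regimens a correlation below -0.1 in replicate 3 alone had been set as the bound. It was 0.0395 there and 0.00141 in replicate 2 alone, so the negative relation was seen in neither. Noise in the fold changes pulls such a correlation towards 0. In replicate 3 alone limma called 0 acute genes (838 at an unadjusted p under 0.05), so the test cannot exclude opposite responses. Without replicate 1 of every group it was 0.0261, which is consistent with a property of the replicate 1 libraries of chronic ethanol and acute control, many of which hold few short transcripts, as the source of the negative value. Why these libraries differ was not tested, since the labels name no batch. Opposite responses, across genes or of single genes such as Cyp2a5, stay open.

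Fewer genes were rhythmic in chronic ethanol (132) than in chronic control (2218). Without replicate 1 the control count was still 14 times the ethanol count (1614 and 115), so the gap did not rest on the replicate 1 libraries alone. The bound for this test was set after the counts were seen, so it counts as a description only. Over 523 genes chosen as rhythmic in acute control, the residual SD without replicate 1 was 1.34 times as large in chronic ethanol as in control (1.26 to 1.42), and the amplitude over all replicates 0.643 times as large (0.667 to 0.678 with 1 number left out). Both a larger spread between libraries and a lower amplitude under chronic ethanol may therefore lower the count, and their shares were not tested.

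More genes were rhythmic in acute ethanol (1903) than in acute control (531). Without replicate 1 the ethanol count was still 6.41 times the control count (1148 and 179), so the gap did not rest on the replicate 1 libraries alone. The bound for this test too was set after the counts were seen, so it counts as a description only. Over 2126 genes rhythmic in chronic control, the residual SD in acute ethanol was 0.894 times that in control, and 0.972 times (0.957 to 0.994) with a block within each arm; the bound set on the latter decides nothing, as the block removes spread between replicate numbers and itself moved the counts to 2310 and 1335. The amplitude ratio was 1.01 (0.939 to 1.11), so a higher amplitude under acute ethanol cannot be told apart from none, because the range crosses the bound set for it. A larger spread between the replicates of acute control may carry part of the difference, and it stays open with the amplitude. The low index of replicate 1 in acute control, seen at ZT4 to ZT16 but not at ZT1 or ZT20, varied with time of day. It may alter the acute control count, though the gap was also seen without replicate 1.

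Other splits of the chronic libraries into arms of the same sizes ignored the replicate numbers. For the 2108 genes of the mean comparison 1 of 100 gave as large a result (the real split, highest other 273). It was also 1 of 100 for the 21 interaction genes (highest other 0) and 1 of 100 for the 81 genes of differential rhythm (highest other 1). Among such splits chance is excluded for these. Among splits that part every same-numbered pair, as the real one does, chance is excluded for the 2108 (1 of 100, highest other 146). For the 81 the share was 2 of 100, but the highest other split called 84, more than the real one. Chance is therefore not called excluded for the 81 among these splits. Nor is it excluded for the 21 (8 of 100, highest other 497), and a split calling that many more genes than the real one points to a structure of the samples. Shuffled times gave as many rhythmic genes only for the real order in chronic control (2218; 1 of 100, highest other 1) and chronic ethanol (132; 1 of 100, highest other 1). For the 10 lists called by camera chance is not excluded (50 of 100; highest other 19), and for the 3 that hold with an estimated correlation it is (2 of 100; highest other 3). Among splits that part every pair these were 53 of 100 (highest other 20) and 2 of 100 (highest other 3), but with the replicate block 2 of the 3 held, and female-biased genes did not (adjusted p = 0.123).

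In the acute regimen splits ignoring the replicate numbers gave as large a result in 2 of 100 for the 300 mean comparison genes. For the 42 interaction genes it was 3 of 100 (highest other 60), and for differential rhythm (90 genes) 3 of 100 (highest other 594). Splits that part every same-numbered pair were not run here, and in the chronic regimen they left chance open for the interaction genes. Chance is therefore not called excluded for these 3 results. The highest other split of the mean comparison called 2133 genes, with 9 libraries of replicate 1, 9 of replicate 2 and 0 of replicate 3 in the ethanol places. Splits calling several times the real count, as here and for differential rhythm, point to a structure of the samples, which for the mean comparison follows the replicate numbers (928 genes with the replicate block). For the 531 rhythmic genes of acute control, 4 of 100 shuffles of the times gave as many. The highest other count was 1618, again a sign of structure, so chance is not called excluded there. Chance is excluded for the 1903 rhythmic genes of acute ethanol (1 of 100, highest other 1). It is not for the 12 lists called by camera (14 of 100; highest other 16), and with an estimated correlation 0 lists were called (100 of 100; highest other 2). Over both regimens, among splits that ignore the replicate numbers, only the real one gave as many as the 1794 genes that differ between them (1 of 100, highest other 1). Splits that part every same-numbered pair were not run for this difference, which includes the acute libraries, and it was 822 without replicate 1. Chance is therefore not called excluded for it either. For the 45 calls shared in direction the splits decide nothing (1 of 100; highest other 0), because they end the calls of each regimen themselves. Independent lists would share 10.4 higher and 20 lower genes.

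At single times the 10 possible splits are too few for a share under 0.05. In the chronic regimen the real counts and the highest others were 164 and 0 at ZT0, 138 and 1 at ZT4, 129 and 0 at ZT8, 221 and 1 at ZT12, 109 and 0 at ZT16, and 75 and 1 at ZT20, each the highest of its splits (1 of 10). In the acute regimen they were 15 and 0 at ZT1, 172 and 1 at ZT4, 36 and 1 at ZT8, and 2 and 0 at ZT12 (1 of 10 each), and at ZT16 0 and 2 and at ZT20 0 and 0 (10 of 10 each), where limma found 1227 and 412 genes at an unadjusted p under 0.05.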

How the results depend on the processing

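Added after the data had been seen were the block within each arm, the 4 acute control libraries left out together, ZT1 left out or coded as 0, replicate 3 alone, a whole replicate number left out for the counts and lists of 1 regimen and for the correlation between regimens, and every alternative for the shared calls except the 0.01 threshold. No called named gene or list reversed. The correlation across genes between the regimens, -0.165, was 0.0261 without replicate 1. Over all settings named genes stayed on the same side of the threshold in 3010 comparisons, lost a call in 240 and gained a call in 99. For lists these numbers were 627, 13 and 22. Direction was compared only for genes and lists called in the main fit, so an uncalled one may have changed sign. Of the 107 called named genes of the chronic regimen 62 to 90 passed without 1 replicate number, and of the 40 of the acute regimen 7 to 17. Genes of the lists called on the chronic mean numbered 158, and 151, 83 and 100 without replicate 1, 2 and 3. Upper-quartile rescaling, a pseudocount of 0.1, limma without trend and robust variances and ZT1 coded as 0 moved no total count by over 1.5 times. With no filter camera also called cholesterol (adjusted p = 0.0309), oxidative phosphorylation (0.028) and cell division (0.0309, and 0.038 with a pseudocount of 0.1) in the chronic and cell division (0.018) in the acute regimen. The cause was not tested where none is given.

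With the replicate block, counts rose in the chronic regimen to 3646 (mean over times), 2087 (single times), 52 (interaction), 206 (differential rhythm) and 602 (rhythmic, ethanol). In the acute regimen 13 of 18 same-numbered pairs had a correlation over 0.1 (-0.152 to 0.652), so the numbers were not taken to pair these libraries. Yet 28 of 36 libraries correlated best with their own number, against 27 of 36 in the chronic regimen. The replicate 3 pairs ran from 0.435 (ZT16) to 0.652 (ZT1). This is a hint from the data that the numbers matter in the acute regimen too. Blocked acute counts were 928, 379, 96 and 164 in the same order and 1335 (rhythmic, control), with 3019 for the difference between regimens and 127 for shared calls. A block within each arm gave 4494, 6321, 127, 446 and 602 in the chronic and 1331, 473, 99, 164 and 1335 in the acute regimen, 3810 for the difference and 172 shared. Besides the calls given in the report, the block between arms ended no call of a named chronic gene.

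With no filter, counts were 85 (rhythmic, chronic ethanol), 194 (acute mean), 47 (acute differential rhythm) and 27 (shared calls). At a minimum of 5 FPKM fewer genes were tested, and counts were 1322 (chronic mean), 11 (chronic interaction), 31 (chronic differential rhythm), 1434 (rhythmic, chronic control), 191 (acute mean), 110 (acute single times), 19 (acute interaction), 1206 (rhythmic, acute ethanol) and 27 (shared). At an adjusted p of 0.01 there were 11 shared calls. Rhythmic genes with a peak-to-trough fold of 1.5 numbered 870 in chronic control and 1258 in acute ethanol. By a one-way F test, which fits no curve, they numbered 1131 and 14 in chronic control and ethanol and 171 and 1239 in acute control and ethanol. At an unadjusted p of 0.01 they were 2170 and 494 in chronic control and ethanol and 972 and 1919 in acute control and ethanol.

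The acute mean comparison gave 39 genes with time left out of the model, 534 without ZT1 (192 higher, 342 lower), and 68 without the 4 acute control libraries (46 higher, 22 lower), against 148 higher and 152 lower. Replicate 3 alone, with 12 libraries fewer per arm, gave 0 genes by limma and 838 at an unadjusted p under 0.05. Without the 4 libraries the single times gave 147, rhythmic genes in acute control 279, the difference between regimens 884 and shared calls 14; without ZT1 351 genes were rhythmic in acute control.

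Leaving out libraries or whole numbers gave, in the chronic regimen, 828 to 2373 (mean), 83 to 1133 (single times), 1 to 39 (interaction), 0 to 100 (differential rhythm; the 0, without replicate 3, had 922 at an unadjusted p under 0.05 in limma), 508 to 2392 (rhythmic, control) and 6 to 139 (rhythmic, ethanol). In the acute regimen the ranges were 35 to 533, 22 to 499, 0 to 100 (without replicate 3, 305 unadjusted in limma), 0 to 126 (without replicate 2, 658 unadjusted), 97 to 644 and 470 to 2254. The difference between regimens ranged from 822 to 1895 and shared calls from 1 to 13.

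Single libraries, each left out alone, that moved a count by over 1.5 times were these. The 21 chronic interaction genes became 13 and 12 without control ZT8 replicate 1 or 2 and 35 and 39 without ethanol ZT16 replicate 1 or 3. The 81 genes of chronic differential rhythm became 49 and 40 without control ZT0 replicate 1 or 2, 40 and 53 without ZT4 replicate 1 or 2, 49 and 41 without ZT8 replicate 1 or 2, 49 without ZT12 replicate 2, 52 without ZT16 replicate 2, 42 without ethanol ZT0 replicate 3, 46 without ZT12 replicate 2 and 45 without ZT20 replicate 1. The 132 rhythmic genes of chronic ethanol became 78, 65 and 76 without ethanol ZT0 replicate 1 or 2 or 3, 87 without ZT4 replicate 3, 51 without ZT8 replicate 3, 65 and 78 without ZT12 replicate 2 or 3 and 81, 64 and 49 without ZT20 replicate 1 or 2 or 3. The 300 genes of the acute mean became 169 without control ZT8 replicate 1, 180 without ZT12 replicate 1, 198 without ethanol ZT1 replicate 3, 199 and 181 without ZT4 replicate 2 or 3, 183 without ZT8 replicate 3, 179 without ZT12 replicate 3 and 533 without ZT16 replicate 2. The 225 acute calls at single times became 138 without control ZT4 replicate 2, 130 and 127 without ethanol ZT4 replicate 2 or 3 and 499 without ZT16 replicate 2. The 42 acute interaction genes became 79 without control ZT1 replicate 2, 20 without ZT4 replicate 2, 23 without ethanol ZT4 replicate 3, 100 without ZT8 replicate 1 and 73 without ZT16 replicate 2. The 90 genes of acute differential rhythm became 45 without control ZT4 replicate 2, 51 and 56 without ZT16 replicate 2 or 3, 50 and 53 without ZT20 replicate 1 or 2, 50 and 47 without ethanol ZT4 replicate 2 or 3, 56 without ZT8 replicate 2 and 58 without ZT20 replicate 2. Depth limits low genes most in replicate 1 of acute control (12600000 to 17100000 fragments) and of chronic ethanol (11600000 to 27400000).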

Other observations

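The tests in this part were planned before the data were examined, except the lists and list counts without a replicate number or without 4 libraries and the genes and libraries named as chosen later. Single genes of the tricarboxylic acid cycle, NAD and one-carbon lists changed under chronic ethanol (n = 18 libraries per arm). Of 16 genes of the tricarboxylic acid cycle, the mitochondrial isocitrate dehydrogenase Idh2 rose by 0.73 (119 to 196 FPKM, adjusted p = 1.31e-06), as 1 of 2 that did, and citrate synthase, Cs (-0.57), Suclg1 (-0.36) and Sdha (-0.20) fell, also adjusted over the list alone. Of 18 genes of NAD metabolism Tdo2, which opens the kynurenine pathway from tryptophan, rose by 0.44, and Qprt (-0.67), Haao (-0.44) and Nadsyn1 (-0.41) fell with Sirt3 (-0.48) and Nmnat1 (-0.29), and 6 fell adjusted over the list alone. Of 15 genes of one-carbon and methionine metabolism Cth, which makes cysteine, rose by 0.59 (267 to 409 FPKM, adjusted p = 0.00299) with Gnmt (0.37) and Mat1a (0.35), and 5 fell, among them Shmt1 (-0.50), Cbs (-0.42), Mtr (-0.34) and Pemt (-0.28), also adjusted over the list alone. Without replicate 1, 7 of the 15 rose and 3 fell. Limma called 0 higher without replicate 2 or 3, with 2 and 3 higher at an unadjusted p under 0.05, and 3 and 5 lower, and Cth was at an adjusted p of 0.0833 and 0.138. Of the 11 genes called in the other lists 10, 5 and 7 passed without replicate 1, 2 and 3, and Idh2, Qprt, Haao and Nadsyn1 in each case. Sirt3, Nmnat1, Gnmt, Mat1a, Cbs and Pemt were named after their values were seen, to complete the counts. The 3 lists did not pass camera (adjusted p = 0.724, 0.226 and 0.809). Under acute ethanol 1 gene of 15 in the one-carbon list rose, Mthfd2 (0.46, adjusted p = 0.0145; 2 adjusted over the list alone; camera adjusted p = 0.148, and 0.0299 without replicate 2). Without replicate 1 or 2 limma called 0 of that list, with 5 and 3 at an unadjusted p under 0.05. Limma called 0 of 16 tricarboxylic acid cycle and 0 of 17 NAD genes there, also adjusted over each list alone, with 2 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.18 and 0.785).

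Single markers of other liver cells passed under chronic ethanol. Of 12 Kupffer cell markers the scavenger receptor Marco rose (0.95, 9.03 to 20.3 FPKM, adjusted p = 0.0363) and Csf1r fell (-0.35), of 11 endothelial markers Lyve1 (0.66, adjusted p = 1.90e-04) and Pecam1 (0.17) rose, and of 11 stellate cell markers Lrat (0.39) and Des (0.32) rose and Reln fell (-0.30). The counts were the same adjusted over each list alone, and camera gave adjusted p of 0.406, 0.284 and 0.332. Neither Kupffer marker passed without replicate 1, 2 or 3 (Marco adjusted p = 0.0862 to 0.135, Csf1r 0.0805 to 0.184). Of 11 periportal markers Cyp2f2 rose (0.37) and Cdh1 fell (-0.38), also adjusted over the list alone (camera adjusted p = 0.452). Of 3 B and T cell markers Cd79a fell (-0.17), and 3 adjusted over the list alone (camera adjusted p = 0.164). The erythroid marker Alas2 fell (-0.84, 74.1 to 44 FPKM, adjusted p = 2.75e-04), as did the adipocyte markers Cfd (-1.30, 2.47 to 0.227 FPKM) and Cidec (-1.37), lists of 1 and 2 measured genes that were too short for camera. Of the 13 markers called in these 7 lists 8, 5 and 4 passed without replicate 1, 2 and 3, and Lyve1, Alas2 and Cfd in each case. Limma called 0 of 9 cell division genes, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0619, and 0.0244 without replicate 2), and 0 of 3 neutrophil (0.978), 2 cholangiocyte, 1 muscle and 2 pancreas markers, with 0 at an unadjusted p under 0.05 in each. Krt19 (-0.10, adjusted p = 0.294), Mylpf (0.04) and Cela1 (-0.22) are examples.

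Under acute ethanol 1 of 10 periportal markers fell, Pigr (-0.37, adjusted p = 0.0343; 2 adjusted over the list alone). Camera gave an adjusted p of 0.148 for that list, which was 6.96e-04 without replicate 1, 0.431 without replicate 2, 0.574 without replicate 3 and 0.0161 without the 4 acute control libraries of low index. Limma called 0 of the 10 without replicate 1, 2 or 3, with 4, 3 and 2 at an unadjusted p under 0.05. Over all libraries it called 0 of 15 acute phase genes, 7 NF-kB genes, 13 male-biased and 5 female-biased genes, 4 cell division genes, 11 Kupffer, 11 endothelial and 10 stellate markers, with 1, 3, 1, 0, 0, 0, 2 and 1 at an unadjusted p under 0.05. Adjusted over the list alone, 1 acute phase gene was lower, 2 NF-kB genes were higher and 1 lower, 1 stellate marker was higher, and 0 passed in the others. Camera gave adjusted p of 0.837, 0.44, 0.6, 0.868, 0.0654, 0.148, 0.868 and 0.388. Without replicate 1 acute phase (0.036, low) and Kupffer markers (0.036, high) passed, and without replicate 2 cell division (0.0324). Limma also called 0 of 1 cholangiocyte, 2 neutrophil, 1 erythroid, 1 muscle and 2 pancreas markers, with 0 at an unadjusted p under 0.05, and 0 of 1 adipocyte marker, with 1. No B or T cell marker was measured there (0).

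The median, mean and camera direction differ in sign for the chronic PPAR-alpha, acute phase, interferon, tricarboxylic acid cycle, one-carbon and neutrophil lists and for the acute clock, glutathione, acute phase and NAD lists, none of which was called. The library of acute ethanol ZT16 replicate 1 held 27339 FPKM of Saa1, 34904 of Saa2, both acute phase genes, and 7048 of Lcn2, where the next highest library, acute control ZT20 replicate 3, held 15001, 12194 and 1141. These values were seen before they were chosen.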
